A study of Mus musculus with 2 samples.

How the data were processed

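Bulk mRNA libraries of classically activated, bone-marrow-derived macrophages from Ninj1 wild-type and knockout mice were prepared with a directional kit, per the labels' protocols. The labels give M-CSF doses that differ from each other, so none is stated. The deposited table holds a normalized signal per gene, which the authors made from read counts divided by 1 size factor per column. That reading rests on the values: 100% of them are whole multiples of the column's smallest step within a tolerance of 0.01 reads. A single read was worth 1.26 to 1.62 normalized counts. The mouse build mm10 and StringTie are listed per the submitters' processing notes, without roles. The aligner, counter, annotation and normalizing tool are not given in the sources used here. Between 71.9% and 74.6% of low recovered counts were even, so mates of a pair appear to be counted separately and depth in fragments is below depth in reads.

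The table had 17271 rows, of which 1 named no gene and was left out (0.0272% to 0.0366% of a column). Of the 17270 genes, 522 were at 0 in all columns. Spreadsheet software had turned 19 symbols into dates, and those genes were tested but not named. Entrez identifiers matched the reference for 97.2% of genes, and transcript length and GC content were found for 15292. Gene positions come from the reference assembly GRCm38, the same build as mm10. Columns without KO in the name were taken as wild type. Depth was 46798381 to 62684262 recovered reads, and the 10 most abundant genes took 9.15% to 9.62%.

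The design fixed before the data were examined assumed 1 library per genotype and held no test. It gave a count of genes at least 2-fold apart on log2(normalized count + 1), the median of each of 37 fixed gene lists with its percentile among 10000 random lists matched on expression in 20 bins, and a naming rule. Because the table held 2 columns per genotype, a test was added after it was seen: limma 3.58.1 with an intensity trend on log2(normalized count + 1), with Benjamini-Hochberg adjustment and calls at adjusted p below 0.05. Log2 ratios are knockout minus wild type on that scale, which understates the change of low genes. Genes needed at least 20 reads in a column, which kept 12872. Residual degrees of freedom were 2 and limma's prior added 12.2. Alternatives were edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, a pseudocount of 0.1, centring on the median log2 ratio, TMM scaling, no filter, at least 100 reads, other fold thresholds, removal of each column's GC and length trend, a block on the column number and leaving out each column. With a column left out, the lone column of a genotype was assumed to vary like the other genotype. edgeR called 204 genes higher and 176 lower, sharing 347 of the 375 limma calls. DESeq2's filter on low counts gave an adjusted p to 8380 of the genes kept, 336 of the limma calls among them, and a gene without one is not counted as a lost call. The common biological coefficient of variation was 7.22%.

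The naming rule took Ninj1, 11 inflammation genes and up to 4 members per list with the largest absolute ratio. It also took the 12 largest ratios in each direction among genes with at least 100 reads in a column, passing over 1 clone symbol. Ninj1, its listed neighbours and sex-linked genes were kept out of those 12 and described apart. Other members were named because they were called, after their values were seen. Folds against 0 used a floor of 3 reads per column, and floors cover counting error only. The tests were tested on simulated data with 200 changed genes. For the knockout against wild type over 12704 genes, limma recovered 75% of 100 genes changed 1.5-fold and 98% of 100 changed 2-fold, with 4 false calls. Over 12748 genes where nothing changed it made 0 calls. The simulated columns held no GC or length trend and no deviation shared by the genes of a column. Changed genes were drawn only from those averaging over 100 reads. These rates therefore need not hold for the real columns. R 4.3.3, Python 3.11.15, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Every symbol had 1 row, so no alternative that counts transcripts apart was run.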

Results

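Messenger RNA was profiled by directional bulk RNA sequencing in bone-marrow-derived macrophages of Ninj1 wild-type and Ninj1 knockout mice. Ninj1 encodes ninjurin 1, a cell-surface protein known for adhesion and for plasma membrane rupture in lytic cell death. Marrow cells of mice aged 6 weeks were grown into macrophages with the growth factor M-CSF over 7 days and then activated with lipopolysaccharide at 500 ng/ml and interferon-gamma at 20 ng/ml, a combination that produces classically activated macrophages. The stated purpose was to relate loss of Ninj1 to macrophage activation through the expression of inflammation-related genes. Each genotype was registered as 1 sample but the deposited table holds 2 columns per genotype. The columns held between 46798381 and 62684262 reads assigned to genes. The 2 columns of a genotype differed by far more than counting noise, with a chi-square per gene of 21.8 in wild type and 14.1 in the knockout, where counting noise alone would give about 1. Allowing 2 reads per fragment the values are 10.9 and 7.05. Nothing in the sources used here says whether they came from separate mice, cultures or library preparations, so the p-values measure only the spread between these columns, which may be technical.

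Ninj1 itself (Entrez 18081; mm10 chromosome 13, 49187529 to 49196251) was measured at 30004 ± 1632 normalized counts in wild type and 3802 ± 401 in the knockout (SD, n = 2 columns each). The knockout level was 12.7% of wild type, a log2 ratio of -2.98 (SE 0.08, limma adjusted p = 1.80e-11), which matches the genotype labels. Gene-level counts do not show which exons the remaining reads came from.

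By limma the knockout columns held more transcripts of Il6, Il1a, Cxcl1, Cxcl2, Cxcl3 and 4 MHC class II genes, and fewer of Fn1, Col1a1, Col1a2 and the mannose receptor Mrc1. Fn1, which encodes fibronectin, fell 11.9-fold. Cxcl1, a neutrophil chemoattractant, rose 2.16-fold, and Il6 rose 1.41-fold. Nos2, Tnf, Il1b, Cxcl9, Cxcl10 and Ptgs2, standard readouts of classical activation, did not pass the test, though DESeq2 called Tnf, Il1b and Ptgs2 higher. Of 12872 genes kept, 56 were at least 2-fold higher and 176 at least 2-fold lower in the knockout. The 2-fold threshold was fixed before the data were examined, but the scale it was applied to was not. Among genes with at least 100 reads in a column the numbers of such genes were 6 and 14. Over all genes kept they were 84 and 201 without wild-type column 1, 124 and 290 without wild-type column 2, 87 and 240 without knockout column 1 and 93 and 282 without knockout column 2. The limma test across the 4 columns, added after the table was seen, called 215 genes higher and 160 lower, with median sizes of 1.28-fold and 1.40-fold. Of the 12872 genes, 2544 had an unadjusted limma p under 0.05, the background for such counts in the lists below. In all, 6583 genes (51.1%) had columns of the genotypes that did not overlap, against 33.3% by chance for 2 against 2. The calls rested heavily on single columns. Without wild-type column 1, 18 genes were called higher and 3 lower, and without wild-type column 2, 355 and 265. Without knockout column 1 the counts were 14 and 9, and without knockout column 2 they were 59 and 108. Ratios also followed transcript composition. The median log2 ratio went from 0.12 in the eighth of genes with the lowest GC content to -0.09 in the highest, and removing each column's GC and length trend left 128 genes called higher and 97 lower.

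**Figure D1:**
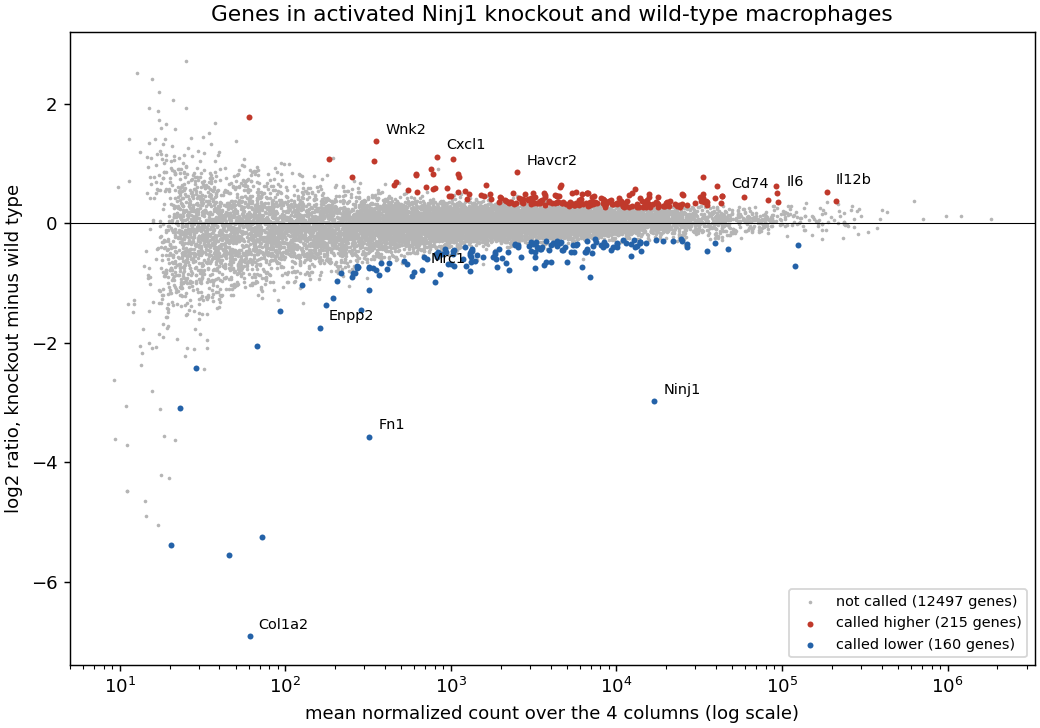
Log2 ratio of knockout to wild type against the mean normalized count over 4 columns (log scale), 1 point per gene. Red points are the 215 genes called higher and blue points the 160 called lower by limma, grey points the 12497 genes not called. Ninj1 lies at -2.98 and Col1a2, the lowest called gene, at -6.91. Both knockout columns of Col1a2 were at 0, so its ratio is set by the pseudocount of 1.

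**Figure D2:**
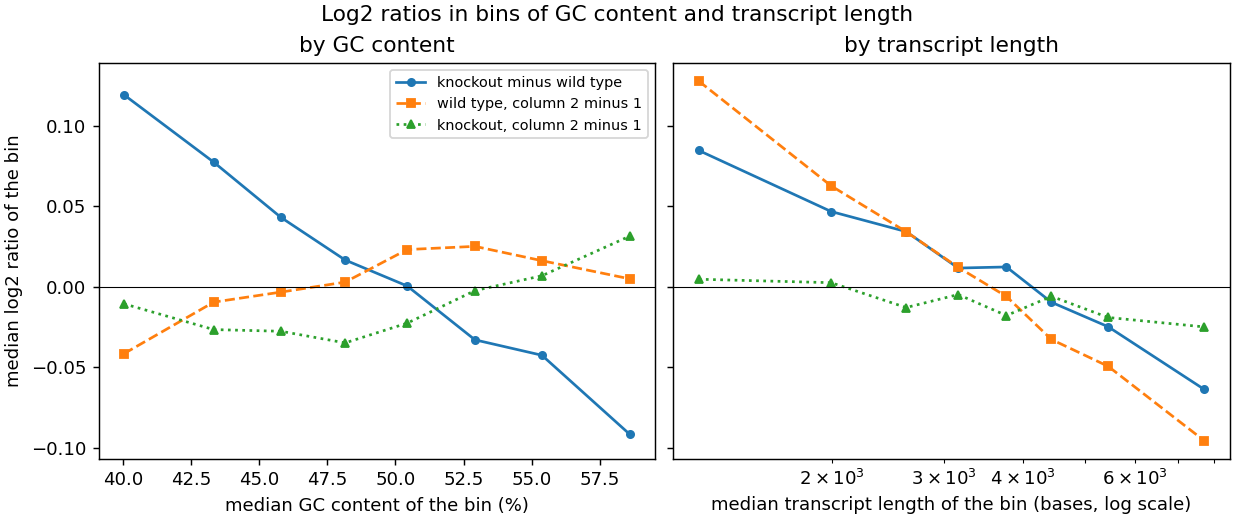
Median log2 ratio in 8 bins of genes by GC content (left) and transcript length (right, log scale), for knockout against wild type and for column 2 against column 1 within each genotype. The knockout to wild-type ratio goes from 0.12 to -0.09 with rising GC content, and within wild type the columns differ by 0.13 to -0.10 with rising length.

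Chemokines lay high as a group, and cytokines did so with all columns in. Among 21 inflammatory cytokines measured, 4 rose, none fell and 17 did not pass the test (8 higher and 1 lower when adjusted over the list alone). The list's median log2 ratio of 0.17 lay at percentile 99.99 of 10000 random lists of like expression. It was only 0.0932 (percentile 89.2) without wild-type column 2. Il1a rose by 0.76 (limma adjusted p = 0.00565), Il6 by 0.50 (adjusted p = 0.00565), Il12b by 0.53 (adjusted p = 0.0333) and Il15 by 0.29 (adjusted p = 0.0492). Il6 went from 77379 ± 422 to 109500 ± 3863 normalized counts and Il12b, the p40 chain of interleukins 12 and 23, from 151170 ± 2351 to 220431 ± 47675 (SD, n = 2 columns). Tnf had a log2 ratio of 0.29 (adjusted p = 0.0833), Il1b of 0.28 (adjusted p = 0.121) and Lif, against the list, of -0.61 (adjusted p = 0.108). Some settings called more cytokines. DESeq2 called 5 higher, Tnf and Il1b among them, and limma with a block on the column number called 6 higher and 1 lower. Among 19 chemokines, 5 rose, 1 fell and 13 did not pass (8 higher and 1 lower adjusted over the list alone), with a median of 0.22 at percentile 99.99. It was 0.13 (percentile 99.2) without knockout column 1, and limma called 6 higher without wild-type column 2. Cxcl1 rose by 1.11 (adjusted p = 0.00565), Cxcl3 by 0.82, Cxcl2 by 0.63, Ccl3 by 0.61 and Ccl22 by 0.45, while Ccl8 fell, with a log2 ratio of -0.56. Cxcl9 (0.19) and Cxcl10 (0.13), induced by interferon-gamma, did not pass. With the GC and length trend removed, Il12b, Il15 and Ccl22 lost their calls at limma adjusted p = 0.0771, 0.126 and 0.0772. The log2 ratios of Il12b and Ccl22 were then 0.43 and 0.42, against 0.53 and 0.45 before. Il1a, Il12b, Il15, Cxcl1, Cxcl3, Ccl3, Ccl22 and Ccl8 lost their calls without wild-type column 1; Il12b, Il15, Ccl22 and Ccl8 without wild-type column 2 or without a filter; Il6, Il12b, Il15, Ccl3, Ccl22 and Ccl8 without knockout column 1; Il15, Cxcl3 and Ccl22 without knockout column 2; Il15 by edgeR or with a pseudocount of 0.1; Il1a, Il12b and Ccl22 by DESeq2; Il15 and Ccl22 with TMM scaling or with at least 100 reads. The call of Cxcl2 passed under each setting.

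MHC class II genes lay high as a group. Of 12 genes of class II presentation, 4 rose, none fell and 8 did not pass (8 higher adjusted over the list alone), with a median log2 ratio of 0.33 at percentile 100. The median was 0.19 (percentile 99.9) without knockout column 1, and DESeq2 called 5 higher. The 4 were H2-Eb1 (0.53, limma adjusted p = 0.0117), H2-Aa (0.49, adjusted p = 0.00565), the invariant chain Cd74 (0.46, adjusted p = 0.00686) and H2-Ab1 (0.32, adjusted p = 0.0262). All 4 stayed called with the GC and length trend removed, with the list median at 0.31, and all 4 lost the call without wild-type column 1 or without knockout column 1, with H2-Ab1 also lost without knockout column 2. Dendritic cells also carry class II. Of their 8 markers Xcr1 (0.51), Ccr7 and Ccl22 rose (3 higher and 1 lower adjusted over the list alone), with 4 ratios above 0 and 4 below and a median of 0.084 at percentile 84.7. Their median was 0.24 (percentile 99.3) without knockout column 1, 0.0123 (percentile 57) without knockout column 2, -0.0673 (percentile 35.3) without a filter and 0.45 (percentile 100) with at least 100 reads. Of 18 class I presentation genes, the chaperone Pdia3 rose (0.36) and the other 17 did not pass (1 higher adjusted over the list alone; 3 higher without wild-type column 2 and by DESeq2). Pdia3 lost its call without wild-type column 1, without knockout column 2, with the GC and length trend removed or without a filter; Pdia3 and Xcr1 without knockout column 1.

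**Figure D3:**
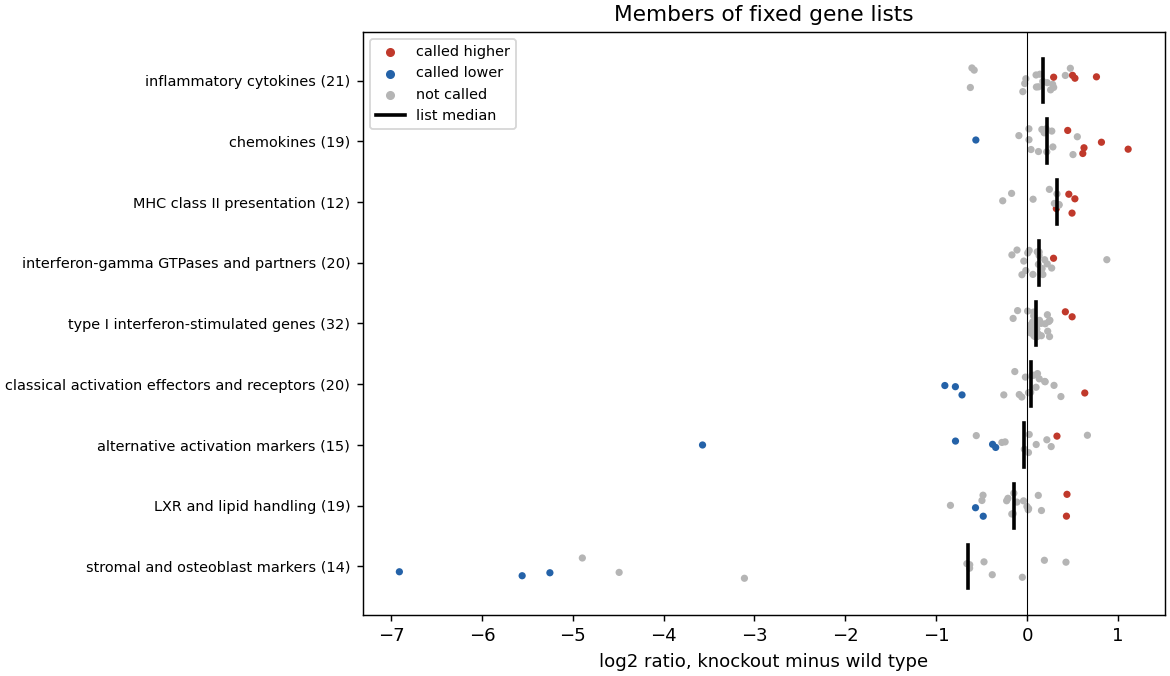
Log2 ratio of knockout to wild type for the measured members of 9 fixed gene lists, 1 point per gene, with the number measured in parentheses and the list median as a black bar. Medians lie at 0.17 for cytokines, 0.22 for chemokines, 0.33 for MHC class II and -0.65 for stromal markers.

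Interferon-induced genes mostly did not pass. Of 32 type I interferon-stimulated genes, Ifit3 (0.42) and Ifit3b (0.50) rose and 30 did not pass (5 higher adjusted over the list alone; 3 higher without knockout column 2 and 6 higher by DESeq2), with 30 ratios above 0 and a median of 0.10 at percentile 94.3. The median was 0.11 (percentile 98.2) without wild-type column 1 and 0.11 (percentile 98.3) without knockout column 1, while the percentile was 68.7 without knockout column 2 and 81.1 with the GC and length trend removed. Ifit3 and Ifit3b are near-identical copies whose reads the counting could split, so their values are uncertain. Of 20 interferon-gamma GTPases and partners, Tgtp1, itself 1 of a near-identical pair, rose (0.29) and 19 did not pass (1 higher adjusted over the list alone), with a median of 0.13 at percentile 97.7. That median was 0.11 (percentile 86.5) without wild-type column 2, 0.12 (percentile 97) without knockout column 1, 0.11 (percentile 89.8) without knockout column 2, 0.0652 (percentile 67.2) with the GC and length trend removed and 0.12 (percentile 97.4) with at least 100 reads. All 3 lost their calls without wild-type column 1 or without knockout column 1; Tgtp1 without knockout column 2, with the GC and length trend removed or without a filter.

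Classical and alternative activation markers went both ways. Of 20 classical effectors and receptors, the homing receptor Ccr7 rose (0.64, limma adjusted p = 0.00565), 3 fell and 16 did not pass (3 higher and 3 lower adjusted over the list alone; 2 higher and 2 lower without wild-type column 2, 2 higher and 3 lower by edgeR and 2 higher by DESeq2). The 3 were the iron-binding protein Lcn2 (-0.90, adjusted p = 0.00565), Slamf1 (-0.79, adjusted p = 0.0136) and the acute-phase protein Saa3 (-0.72, adjusted p = 0.0231). Lcn2, Slamf1 and Saa3 lost their calls without wild-type column 1 or by DESeq2; Saa3 without wild-type column 2; Slamf1 and Saa3 without knockout column 1. Nos2, the inducible nitric oxide synthase, stood at 254408 ± 4177 normalized counts in wild type and 214120 ± 30269 in the knockout (log2 ratio -0.26, adjusted p = 0.187). Ptgs2, which encodes cyclooxygenase-2, had a log2 ratio of 0.37 (limma adjusted p = 0.0833; edgeR adjusted p = 0.0234, called by DESeq2 too), and Cd86 of 0.12 (limma adjusted p = 0.404). Of 15 alternative activation markers, Cd83 rose (0.33), 4 fell and 10 did not pass (3 higher and 4 lower adjusted over the list alone; 2 higher and 3 lower by DESeq2). The median of -0.03 lay at percentile 26.7. It was -0.0598 (percentile 13) without wild-type column 1, -0.0454 (percentile 22.9) without wild-type column 2, -0.00868 (percentile 38.6) without knockout column 1, -0.10 (percentile 5.07) without knockout column 2, -0.17 (percentile 0.095) with the GC and length trend removed, -0.26 (percentile 0.06) without a filter and -0.00699 (percentile 35.6) with at least 100 reads. Fn1 fell, with a log2 ratio of -3.57 (limma adjusted p = 0.00045), as did Mrc1 (-0.79, adjusted p = 0.0203), the scavenger receptor Stab1 (-0.38) and the interleukin-4 receptor chain Il4ra (-0.35). Stromal cells also make fibronectin, and 3 of 14 stromal markers fell in the same columns. Arg1 stood at 167 ± 73.5 and 109 ± 21.1 normalized counts and did not pass (adjusted p = 0.338). Mrc1, Stab1 and Il4ra lost their calls without wild-type column 1; Cd83 without wild-type column 2, by edgeR, with a pseudocount of 0.1, with TMM scaling or with at least 100 reads; Cd83, Mrc1, Stab1 and Il4ra without knockout column 1; Cd83, Stab1 and Il4ra without knockout column 2 or with the GC and length trend removed; Cd83 and Il4ra without a filter.

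**Figure D4:**
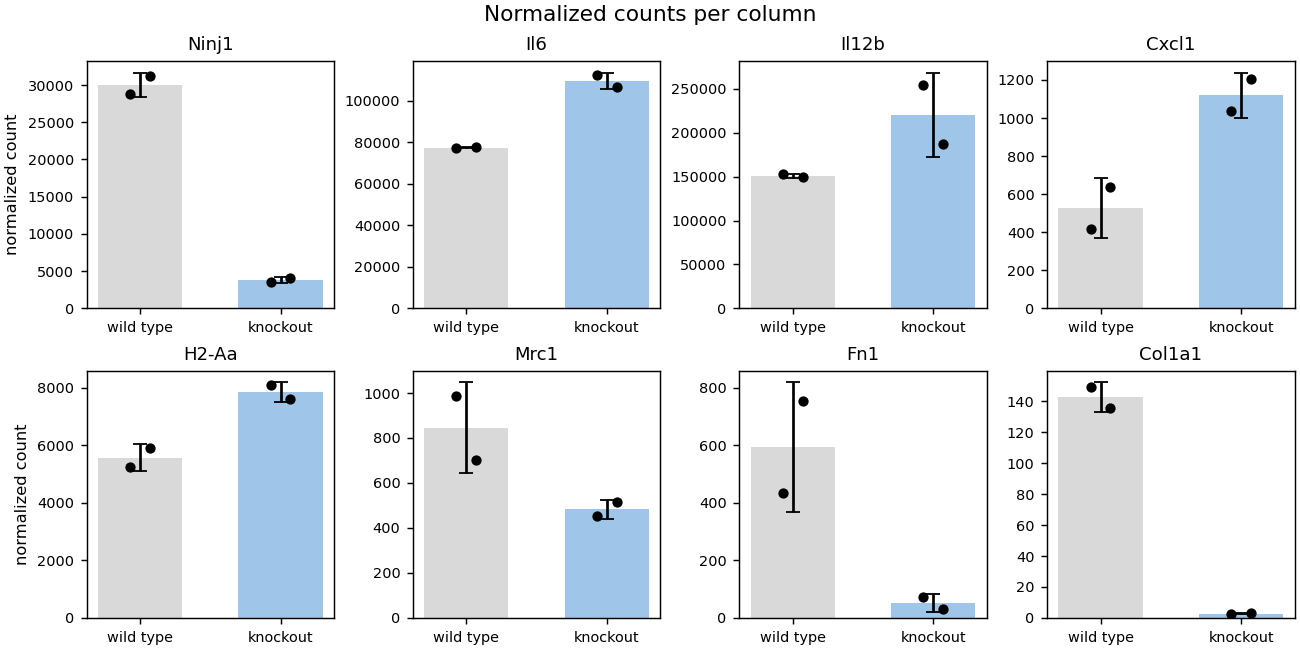
Normalized counts of 8 genes per genotype, with points for the 2 columns, bars for their mean and error bars for the SD. Il6 lies at 77379 in wild type and 109500 in the knockout, and Col1a1 at 143 and 2.77.

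Signalling, cell death and adhesion genes mostly did not pass. None of 32 NF-kB and TLR signalling genes was called by limma, adjusted over all genes or over the list alone, or by edgeR. In all, 3 had an unadjusted p under 0.05 and DESeq2 called 2. With the GC and length trend removed the inhibitors Nfkbie (0.34, adjusted p = 0.0152) and Nfkbib (0.30, adjusted p = 0.0209) were called higher, as they were without wild-type column 2, where Tlr9 was called lower. The list's median of 0.07 at percentile 82.3 was 0.0348 (percentile 41.3) without wild-type column 2 and 0.0395 (percentile 38.6) without knockout column 2. Of 19 inflammasome and lytic cell death genes, Casp1 rose (0.29) and 18 did not pass (1 higher adjusted over the list alone). Among the 19, 9 had an unadjusted p under 0.05. Of 25 adhesion genes, Cd44 (0.37) and Cd9 (0.34) rose, the integrin chains Itga6 (-0.66) and Itgam (-0.37) fell and 21 did not pass (6 higher and 3 lower adjusted over the list alone; 4 higher and 3 lower without wild-type column 2 and 4 higher and 2 lower by DESeq2). Of 24 cytoskeleton and matrix remodelling genes, Timp1 (-0.97), Mmp19 (-0.48) and Mmp14 (-0.37) fell and 21 did not pass (3 lower adjusted over the list alone, 1 higher and 1 lower without wild-type column 2). All 8 lost their calls without wild-type column 1 or without knockout column 1; Timp1 and Mmp19 without wild-type column 2; Casp1, Cd9, Itgam and Mmp14 without knockout column 2; Casp1, Cd9, Itgam and Mmp19 with the GC and length trend removed; Casp1, Itgam, Timp1 and Mmp19 without a filter; Mmp19 with a pseudocount of 0.1, with TMM scaling or with at least 100 reads.

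Lipid-handling genes lay low as a group. Of 19 LXR and lipid-handling genes, the cholesterol exporter Abca1 (-0.57, limma adjusted p = 0.0104) and the transfer protein Pltp (-0.48, adjusted p = 0.0074) fell, the fatty acid receptor Cd36 (0.44) and the lipase Lpl (0.43) rose and 15 did not pass (2 higher and 5 lower adjusted over the list alone; 3 higher and 5 lower without wild-type column 2 and 2 higher and 3 lower by edgeR and by DESeq2). The median of -0.15 lay at percentile 0.05. Scd2 had the largest ratio (-0.84) and did not pass (adjusted p = 0.0776) except without wild-type column 2. Oxidative phosphorylation genes had a median of 0.14 over 29 members at percentile 99.96, with none called by limma or edgeR (2 higher adjusted over the list alone, 10 at an unadjusted p under 0.05, 1 by DESeq2). The median was 0.0771 (percentile 95) without wild-type column 1, 0.22 (percentile 100) without wild-type column 2 and 0.0645 (percentile 91.5) with the GC and length trend removed, and limma called 3 higher without wild-type column 2. Of 24 glycolysis and hypoxia genes Pgam1 passed narrowly (0.36, adjusted p = 0.0499; 1 higher and 1 lower adjusted over the list alone, 1 lower without wild-type column 2 and 1 higher and 1 lower by DESeq2). None of 22 antioxidant genes was called by limma, in either count, or by edgeR, with 5 at an unadjusted p under 0.05 and 1 called by DESeq2. Without wild-type column 2 limma called 2 higher. The list's median of 0.0879 at percentile 84.7 was 0.0434 (percentile 59.3) without wild-type column 1 and 0.18 (percentile 99.5) without wild-type column 2. Of 26 lysosome and phagocytosis genes the efferocytosis receptor Mertk (-0.48) and the inhibitory Fc receptor Fcgr2b (-0.36) fell (1 higher and 4 lower adjusted over the list alone; 1 higher and 2 lower without wild-type column 2, 3 lower with the GC and length trend removed and 1 higher and 3 lower by DESeq2). All 7 lost their calls without wild-type column 1 or without knockout column 1; Pgam1 and Fcgr2b without wild-type column 2; Mertk without knockout column 2; Cd36 and Pgam1 with the GC and length trend removed; Pgam1 by edgeR, without a filter, with a pseudocount of 0.1, with TMM scaling or with at least 100 reads.

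Of 22 unfolded protein and heat shock genes, Dnajb9 (0.50), the ER chaperone Hspa5 (0.37), Hsph1 (0.31) and Hsp90aa1 (0.28) rose, Sesn2 (-0.48) fell and 17 did not pass (7 higher and 2 lower adjusted over the list alone, 5 higher and 1 lower without wild-type column 2 and by DESeq2). Of 30 cell cycle genes Ccnd1 (0.30) rose and Mki67 (-0.52) fell, with the same count adjusted over the list alone. Of 21 p53 and apoptosis genes Bcl2a1b (0.37), which has near-identical copies and is uncertain, rose (1 higher adjusted over the list alone). All 8 lost their calls without wild-type column 1 or without knockout column 1; Ccnd1 without wild-type column 2 or with at least 100 reads; Hspa5, Hsph1, Hsp90aa1, Ccnd1, Mki67 and Bcl2a1b without knockout column 2; Hspa5, Hsp90aa1, Sesn2, Mki67 and Bcl2a1b with the GC and length trend removed; Hsp90aa1 and Ccnd1 by edgeR; Hspa5, Hsp90aa1, Ccnd1 and Mki67 without a filter; Hspa5 and Ccnd1 with a pseudocount of 0.1; Hspa5 with TMM scaling.

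Transcripts of type I collagen were nearly absent from the knockout. Col1a1 stood at 143 ± 9.55 normalized counts in wild type and 2.77 ± 0.354 in the knockout (limma adjusted p = 0.00116), and Bgn, which encodes biglycan, at 90.5 ± 34 and 1.26 ± 1.78 (adjusted p = 0.00736). Col1a2 stood at 122 ± 34.2 and 0, at least 29.2-fold lower against a floor of 3 reads per column (adjusted p = 0.0035). Of 14 stromal and osteoblast markers 3 fell, none rose and 11 did not pass (1 higher and 9 lower adjusted over the list alone), with a median of -0.65 at percentile 0.06, or -1.01 (percentile 0) without a filter. edgeR and limma without a filter each called 6 of them lower, and DESeq2's filter on low counts left none of the 14 with an adjusted p. The median is also -0.65 with members at 0 set at the floor. Dcn (-0.66), Lum (0.19) and Runx2 (0.43) did not pass. The 3 calls were lost without wild-type column 1. These levels are low beside the macrophage genes, and Fn1 was also lower in both knockout columns.

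Among markers of other cell types, Il7r (0.45) rose among 3 T and NK markers, Csf3r (-0.71) fell among 3 neutrophil markers, and Dcstamp (0.64) rose among 10 osteoclast markers (4 higher adjusted over the list alone; median 0.23, percentile 99.93). No member was called by limma or edgeR among 2 B cell, 6 endothelial, 1 erythroid, 2 mast cell and 4 platelet markers measured, with 1 B cell and 1 endothelial marker at an unadjusted p under 0.05, each also called when adjusted over the list alone. Without wild-type column 2, 1 endothelial marker was called lower. Of 13 mitochondrially encoded genes ND2 rose (0.39; 3 higher adjusted over the list alone). edgeR and DESeq2 each called 3 higher. Their median of 0.12 at percentile 93.7 was 0.22 (percentile 99.9) without wild-type column 1, -0.0268 (percentile 25.3) without wild-type column 2 and -0.18 (percentile 0.07) with the GC and length trend removed. None of 30 ribosomal protein genes was called by limma or edgeR, with 5 at an unadjusted p under 0.05 and 1 called by DESeq2 (median 0.13, percentile 99.74). That median was 0.00314 (percentile 27.6) without wild-type column 1, 0.25 (percentile 100) without wild-type column 2 and 0.0642 (percentile 88.9) with the GC and length trend removed, and limma called 6 higher without wild-type column 2. None of 4 histone genes was called by limma or edgeR, with 0 at an unadjusted p under 0.05. Il7r, Csf3r and Dcstamp lost their calls without wild-type column 1; ND2 without wild-type column 2, with the GC and length trend removed or without a filter; all 4 without knockout column 1; Il7r and ND2 without knockout column 2. Xist was read in all columns, at 67910 ± 7960 and 63919 ± 2077 normalized counts.

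The largest ratios outside the lists, by the fixed naming rule, included rises of B3gnt5 (1.08), Cav1 (1.07), Cd226 (1.03), Macc1 (0.91) and the inhibitory receptor Havcr2, also called TIM-3 (0.85, limma adjusted p = 0.00104). Ubd (adjusted p = 0.153), Gcm1 (0.98), Kcna2 (0.98), Bc1 (0.90), Otor (0.86) and Tm4sf5 (0.85) did not pass. On the low side Enpp2, the lysophospholipase autotaxin (-1.75), Tmem267 (-1.45), Steap4 (-1.37), Gem (-1.26) and Creg2 (-1.11) fell. Xlr3b (-1.34), Efnb2 (-1.08), Scarf2 (-1.07), Irs2 (-1.06) and Zfp366 (-1.05) did not pass. Bc1 and Irs2 were called without wild-type column 2 and Xlr3b without knockout column 2. B3gnt5, Cav1, Cd226, Macc1, Enpp2, Steap4, Gem and Creg2 lost their calls without wild-type column 1; Tmem267 and Steap4 without wild-type column 2; B3gnt5, Macc1, Enpp2, Tmem267, Steap4, Gem and Creg2 without knockout column 1; B3gnt5, Cav1, Cd226 and Gem without knockout column 2; B3gnt5 with the GC and length trend removed or with at least 100 reads; Cav1 by DESeq2; B3gnt5, Steap4 and Gem without a filter. Of 11 genes measured next to Ninj1, Card19 rose 1.49-fold (0.57, adjusted p = 0.0015) and Wnk2 2.58-fold (1.37, adjusted p = 0.00174), and 9 did not pass (2 higher adjusted over the list alone), though Bicd2 was called higher with the GC and length trend removed (0.27, adjusted p = 0.0434). Card19, Wnk2, Havcr2, Ccr7, Cxcl2 and Fn1 were called under every setting that gave a value; DESeq2 gave no adjusted p for Wnk2 and Fn1.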

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

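The limma, edgeR, DESeq2, GC and length, leave-one-out and block settings were chosen after the data were seen, as was every setting for the limma calls; the others were fixed before. Ninj1 was called lower under every setting. Without a filter, 595 genes were at least 2-fold higher and 1194 lower, and with at least 100 reads 6 and 14, since low counts give large ratios. At 1.5-fold the counts were 235 and 593, and at 4-fold 5 and 35. Leaving out a column gave 84 to 124 higher and 201 to 290 lower. limma called 122 higher and 100 lower without a filter, where more genes were tested, and 128 and 97 with the GC and length trend removed. DESeq2 called 341 higher and 194 lower among 8380 genes. Without a column, 14 to 355 were called higher and 3 to 265 lower, with fewer columns behind each fit. Of 375 calls, 21 remained without wild-type column 1, 275 without wild-type column 2, 20 without knockout column 1 and 132 without knockout column 2, and 174 of 365 remained with the trend removed. The cause of the differences between single columns was not tested. Some genes that lost their calls with the GC and length trend removed kept most of their log2 ratio. Mmp19 stayed at -0.48, Itgam went from -0.37 to -0.33 and Pgam1 from 0.36 to 0.34. Hspa5 went from 0.37 to 0.33, Mki67 from -0.52 to -0.46 and B3gnt5 from 1.08 to 0.98. Others lost more, with Casp1 going from 0.29 to 0.09 and Bcl2a1b from 0.37 to 0.18.

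Same-numbered columns did not deviate together (correlation across 9920 genes -0.12), so the numbers do not pair them. A block on the number called 322 higher and 280 lower. A crossed pairing called 745 higher and 631 lower.

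Across settings, 8 to 12 list medians lay in the outer 5% of random lists, against 9. The cytokine median was 0.22 with at least 100 reads and 0.0932 to 0.23 without a column. The chemokine median was 0.15 with the trend removed and 0.13 to 0.28 without a column. For interferon-gamma GTPases these were 0.0652 and 0.11 to 0.12, and for oxidative phosphorylation 0.0645 and 0.0771 to 0.22. MHC class II medians were 0.19 to 0.40 without a column and ribosomal protein medians 0.0031 to 0.25. The stromal median was -1.01 without a filter, -0.55 with at least 100 reads, -0.73 with the trend removed and -0.83 to -0.63 without a column. The causes were not tested. Among genes that did not pass, Cd86 turned to -0.0082 with the trend removed, and without a column Kcna2 ranged from -0.17 to 2.13, Lum from -0.0406 to 0.42, Mylip from -0.34 to 0.0519, Tlr9 from -0.32 to 0.0575 and Xist from -0.20 to 0.0371.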

Other observations

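The tests on the ER machinery, on low-read fibroblast genes and on the share of cytokine calls kept were chosen after the results were seen. So were those on the interval around Ninj1 and on neighbouring calls, and the percentile of the joint cytokine and chemokine list. Genes that move proteins into and out of the endoplasmic reticulum were higher together. The list was written after 15 of its 60 genes had been seen among the calls, so the other 45 were tested apart. The 15 were listed afterwards from an earlier look, so others of the 45 had perhaps been seen too. All 45 had ratios above 0, 2 were called higher by limma and 17 when adjusted over the list alone (8 higher without wild-type column 2 and 9 higher by DESeq2). An adjustment over the list alone is not independent evidence. Their median log2 ratio of 0.17 lay at percentile 100 of random lists matched on expression but not on shared regulation. It stayed at percentile 100 with the GC and length trend removed (median 0.13). Within a genotype, the medians of these 45 genes in single columns varied by an SD of 0.0774. Their median log2 ratio with each column left out is not given here. The hypothesis is that this machinery is higher as a group in these knockout columns. Among the genes seen first, Tram1 rose by 0.46, Kdelr2 by 0.44, Sec61b by 0.40 and Dnajc3 by 0.34. All 4 lost their calls without wild-type column 1 or without knockout column 1; Kdelr2, Sec61b and Dnajc3 without knockout column 2; Dnajc3 with the GC and length trend removed or without a filter.

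Havcr2, Havcr1 and Timd4, neighbouring TIM-family receptor genes on mm10 chromosome 11 between 46454931 and 46844333, all rose, by 0.85, 1.78 and 0.83 (limma adjusted p = 0.00104, 0.0404 and 0.0153), as did the adjacent Med7 (0.34). Havcr1, Timd4 and Med7 lost their calls without wild-type column 1 or without knockout column 2; Med7 without wild-type column 2; Havcr1 and Med7 without knockout column 1, with the GC and length trend removed or without a filter. They were chosen after their values were seen, and Havcr1 was low, at 26.2 ± 4.94 and 95 ± 34.5 normalized counts.

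The rise of cytokines and chemokines was set against technical causes. Centring on the median of all genes shifted each ratio by only 0.0034 and left the median of the 9 called members at 0.62 against 0.61, so it was no test of scaling. The 40 cytokines and chemokines together had a median log2 ratio of 0.21 at percentile 100 of random lists. With each column left out the median was 0.18 to 0.23. A factor per column moves all genes alike, so it cannot make a lead over other genes. That follows from arithmetic, and the percentile is no test of it. With the GC and length trend removed the median of the 9 was 0.45, 73.4% of its size, between the bounds fixed for keeping or losing the pattern, so a share of the size cannot be told apart from that trend. After the removal 6 of the 9 members were still called. The 9 had been picked by their calls. With bin medians of only 0.12 to -0.09 by GC content, the trend's removal could hardly undo the larger ratios. The count of 6 is therefore a weak test of the trend as the whole cause. An effect of genotype stays open, untested beyond these columns.

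The low reads of Col1a1, Col1a2 and Bgn may come from the cells or from stromal cells carried over in the wild-type cultures. The GC and length trend was too small to make these low reads, with bin medians of only 0.12 to -0.09 by GC content. Its removal could hardly change the 3 called markers, whose corrected median was -5.55. A second fibroblast list had a median log2 ratio of -0.09 at percentile 21.3, with Lamc1 the only call. Of its 18 members with at least 20 reads, 3 (16.7%, exact 95% interval 3.58% to 41.4%) were below in both knockout columns. That met the bound against carry-over, which was set at the share expected by chance. Over all genes kept, 51.1% had columns that did not overlap in either direction, against 33.3% by chance. The share of all genes below in both knockout columns was not computed. The list's median was -0.16 (percentile 4.32) without wild-type column 1, -0.0343 (percentile 49.6) without wild-type column 2, -0.15 (percentile 6.94) without knockout column 2, -0.0226 (percentile 59.3) with the GC and length trend removed and -0.47 (percentile 0.08) without a filter. That bound excluded little, since its interval is wide and these members have a median wild-type count of 264, which would hide a few stromal cells. The 26 members under 20 reads held 130 and 199 summed normalized counts in the wild-type columns and 40.4 and 45.3 in the knockout columns, 3.84 times as many, and 22 of them were higher in wild type. That fits carry-over but had been glimpsed before it was tested, and Lum (0.19) did not follow it. The like sum over all genes under 20 reads was not computed. Of the 14 stromal markers, 11 lay below in both knockout columns and 1 above. Col3a1 and Postn, not called by limma, were at 0 in both knockout columns, at least 6.9-fold and 5.4-fold lower against the floor. The 14 include the genes that raised the question, so they are no separate test. More genes were at 0 in the knockout columns (1691 and 1839) than in the wild-type columns (1581 and 1536), so low genes may lean this way in general. Carry-over and an effect of genotype both stay open.

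Card19 and Wnk2 lie 6.70 and 39.0 kb from Ninj1. Their mean log2 ratio was 1.10 with the GC and length trend removed against 0.97. Both are rich in GC, at 58.2% for Card19 and 62.4% for Wnk2. The trend by GC content lowers the knockout ratio of such genes, so it runs against their rise. Its removal could hardly have lowered their ratios and was no real test. Of 41 other genes within 5 Mb none was called by limma, against 2.94% called elsewhere (2-sided Fisher's exact p = 0.634), and 0 by edgeR. Of the 41, 3 had an unadjusted limma p under 0.05, as did 2544 of all 12872 genes kept. With the GC and length trend removed Bicd2, 145 kb away, was called higher (0.27), and the crossed pairing of columns called 2 of the 41. Without wild-type column 2 Mylip had a log2 ratio of -0.34. The 41 genes are too few to exclude strain variants carried along with the allele. Genome-wide, 150 called genes had another within 1 Mb against a mean of 166 and a highest of 199 in 1000 permutations. That gives no sign of many linked blocks across the genome. A few blocks could lie within that spread and are not excluded. A local effect of the targeted allele is a candidate explanation that was not tested.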
